A study of Mus musculus with 24 samples.

How the data were processed

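Expression was measured in C2C12 myotubes infected at a multiplicity of 300 with dl312, dl520 or dl928 and harvested 24 h or 36 h later. Per the labels, the RNA was isolated with Trizol, 5 µg were labelled as biotin cRNA, and each of 12 biological samples (2 per group, 6 groups) was hybridized to 2 technical arrays. The deposited values are intensity values, MAS5 signals per the labels, for 45101 probe sets on a linear scale, and the version of MAS5 was not stated. The 2% trimmed mean was 500 on each of the 24 arrays, so that the arrays had been scaled by the authors, and no further scaling was applied. The 3'/5' ratio was 1.09 to 1.38 for beta-actin and 0.805 to 0.969 for Gapdh.

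Signals were taken as log2 of the signal plus 30.65, and the technical arrays of a sample were averaged on that scale. Probe sets were kept when at least 2 of the 12 samples reached the median of all values (log2 7.28, a signal of 125.2), which left 25448. Gene symbols came from the platform annotation. Of the probe sets, 64 were controls, 34945 had 1 symbol, 932 several and 9160 none, and 34754 were matched by Entrez ID to the RefSeq table, by which 0 symbols changed. The brightest kept probe set stood for a gene, which gave 12716 genes from 22098 probe sets. The 3350 kept probe sets without a single symbol were fitted apart.

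Groups were compared in R 4.3.3 with limma 3.58.1, with a mean for each of the 6 groups, an intensity trend in the variance prior (6 residual and 6.12 prior degrees of freedom) and Benjamini-Hochberg adjustment within a comparison. A gene was called at an adjusted p below 0.05. The comparisons were each pair of viruses at each time, 36 h against 24 h within a virus, and the difference between times of each virus comparison. The effect of the shared dl312 samples on the correlation between viruses and on the overlap of calls was simulated 100 times.

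The 21 gene lists, with 657 members, were DNA replication and G1/S, G2/M and mitosis, pocket proteins with E2Fs, cyclins and CDKs, homologous recombination, chromatin, contractile apparatus, calcium handling and energy metabolism, myogenic regulators, myoblast markers, extracellular matrix, p53 targets, apoptosis, interferon-stimulated genes, NF-kappaB targets, immediate early genes, unfolded protein response, heat shock, mitochondrial respiration, ribosome biogenesis, cholesterol synthesis, and atrophy ligases with autophagy. They were tested with camera at a preset correlation of 0.01 and at an estimated correlation. No list passed with the estimated correlation, the lowest adjusted p being 0.059. The genes named were the 8 largest rises and 8 largest falls among called genes whose samples did not overlap between groups (4 and 4 for times and differences between times), leaving out predicted and unnamed genes. Up to 4 called members of a list with the largest change, or the 2 largest where none was called, and the genes of a panel were added. These choices, the lists and the alternatives were made before the data were examined, except for 2 alternatives added later.

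The procedure was tested in 10 simulations of 12716 genes with 200 changed. It recovered 20.8% of genes changed 1.5-fold, 74.2% at 2-fold, 99.4% at 4-fold and 100% at 8-fold, and 4.85% of calls were false. Camera found the changed list in 10 of 10 and a random list in 0, but correlated genes were not tested. The alternatives were other pseudocounts, filters, array scalings, technical arrays, probe set rules and variance priors, a replicate block, fits of only the groups compared, and leaving out each sample in turn. Camera was not run on the fit of 24 separate arrays.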

Results

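C2C12 cells, a mouse myoblast line that fuses into contracting myotubes when serum is withdrawn, were differentiated for 72 h with cytosine arabinoside, a drug that kills dividing cells, and then infected with an adenovirus. The control virus dl312 lacks essentially the whole E1A gene, whose product binds the retinoblastoma family and the acetyltransferases p300 and CBP. The virus dl520 expresses the 12S form of E1A, and dl928 its YH47 mutant (Y47H and C124G). RNA was taken 24 h and 36 h after infection for mouse expression arrays. Each of the 6 groups held 2 samples that the labels call biological replicates, each run on 2 technical arrays. The median signal of an array was 112 to 152. The technical arrays of a sample correlated at r = 0.972 to 0.985. The biological replicates of a group, after averaging these arrays, correlated at r = 0.974 to 0.986, genes not being independent replicates. Replicate differences had an SD of 0.291 to 0.405, above that expected from technical spread in each group. The first principal component held 61.5% of the variance over the 12716 genes tested. Changes are given as folds and as log2 differences of group means ± standard error, with n = 2 samples per group throughout. Signals are means ± SD of the same 2 samples.

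The comparison of dl520 with dl312 at 24 h asks what 12S E1A does to gene expression in myotubes that have left the cell cycle. The largest rises included genes of DNA synthesis. Cyclin E2, which drives entry into S phase, went from a signal of 143 ± 6.16 in dl312 to 5199 ± 1782 in dl520, for Ccne2 (29.3-fold, log2 4.87 ± 0.32). The next were Timeless (26.8-fold, log2 4.74 ± 0.31), which guards replication forks, Mcm5 (24.7-fold, log2 4.62 ± 0.30) of the replicative helicase, Fignl1 (18.1-fold, log2 4.18 ± 0.31) and Uhrf1 (17.9-fold, log2 4.16 ± 0.29), which maintains DNA methylation. They were followed by Cdc6 (16.9-fold, log2 4.08 ± 0.33), which licenses origins, the mitotic helicase Ercc6l (15.9-fold, log2 3.99 ± 0.38) and Mcm3 (15.7-fold, log2 3.97 ± 0.25) of the replicative helicase. The adjusted p of these 8 was 4.96e-06 to 6.89e-05. In dl312 the mean signal of Timeless, Fignl1, Uhrf1, Cdc6 and Ercc6l lay below the filter threshold, so that the size of their folds depends on the constant added to the signal. The largest falls were those of Smim5 (log2 -2.32 ± 0.24), the chemokine Ccl5 (log2 -2.32 ± 0.47), Fam107a (log2 -2.31 ± 0.26) and the muscle AMP deaminase Ampd1 (log2 -2.20 ± 0.53). After them came A4galt (log2 -2.20 ± 0.64), Fam167a (log2 -2.19 ± 0.34), Dmp1 (log2 -2.18 ± 0.50) and Ly6g2 (log2 -2.14 ± 0.50), with adjusted p = 1.23e-04 to 0.0385. In dl520 Ccl5, Ampd1 and A4galt lay below the threshold. Leaving out dl312 replicate 1 ended the calls of Ccl5, Ampd1, A4galt and Ly6g2. Without dl312 replicate 2, calls were lost for Ampd1, A4galt, Dmp1 and Ly6g2. The call of Dmp1 was lost without dl520 replicate 1. Omitting dl520 replicate 2 ended those of Ccl5, Ampd1, A4galt, Dmp1 and Ly6g2. Other settings ended the calls of A4galt and Dmp1 (adjusted p = 0.0513 to 0.327 in all).

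At 24 h with dl520 genes of 5 cell cycle lists were called. Of the DNA replication and G1/S genes, 47 of 50 rose and 3 did not pass (47 rose adjusted over the list alone), with a median log2 change of 2.07. The replication list gave adjusted p = 1.15e-43 by camera and adjusted p = 0.098 with an estimated correlation. Among the G2/M and mitosis genes, 50 of 57 rose and 7 did not pass (53 rose and 1 fell adjusted over the list alone), with Melk (log2 3.70 ± 0.44), the topoisomerase Top2a (log2 3.22 ± 0.40) and the spindle checkpoint kinase Bub1b (log2 3.14 ± 0.38) in front. The mitosis list gave adjusted p = 1.57e-26 by camera and adjusted p = 0.158 with an estimated correlation. In homologous recombination and the replication checkpoint, 23 of 30 rose and 7 did not pass (28 rose adjusted over the list alone), among them Rad51ap1 (log2 3.46 ± 0.39) and the checkpoint mediator Clspn (log2 3.40 ± 0.34). The recombination list gave adjusted p = 1.73e-20 by camera and adjusted p = 0.10 with an estimated correlation. Of the chromatin and DNA methylation genes, 16 of 27 rose and 11 did not pass (22 rose adjusted over the list alone), led by the helicase Hells (log2 3.52 ± 0.26) and Hmgb2 (log2 3.49 ± 0.37). The chromatin list gave adjusted p = 1.23e-12 by camera and adjusted p = 0.127 with an estimated correlation. The list of pocket proteins, E2Fs, cyclins D/E, CDKs and CDK inhibitors was split, as 11 rose, 3 fell and 12 of 26 did not pass (11 and 4 adjusted over the list alone). The E2F and CDK list gave adjusted p = 0.00938 by camera and adjusted p = 0.237 with an estimated correlation. In it E2f1 (log2 2.08 ± 0.29), the cyclin E1 gene Ccne1 (log2 3.08 ± 0.41), E2f7 (log2 2.93 ± 0.27) and the p107 gene Rbl1 (log2 2.18 ± 0.21) rose, and the G1 cyclin Ccnd1 (log2 -0.99 ± 0.21) fell. The retinoblastoma gene Rb1 (log2 -0.12 ± 0.17) and the CDK inhibitors Cdkn1a (log2 -0.37 ± 0.13) and Cdkn1b (log2 0.09 ± 0.20) did not pass. Ccnd1 lost its call without dl312 replicate 2. Leaving out dl520 replicate 2 ended the call of Ccnd1 (adjusted p = 0.0844 to 0.0854 in all).

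In the 3 muscle lists 48 of 113 members fell at 24 h with dl520 and the others did not pass. Myogenin, a transcription factor of terminal differentiation, went from a signal of 8438 ± 1798 in dl312 to 3224 ± 88.7, for Myog (2.57-fold, log2 -1.36 ± 0.17), and Myod1 (4.08-fold, log2 -2.03 ± 0.29), the transcription factor of muscle identity, also fell. Of the myogenic regulators and muscle membrane genes, 17 of 30 fell and 13 did not pass (24 fell adjusted over the list alone), with Myf6 (log2 -1.84 ± 0.44) and Myf5 (log2 -1.58 ± 0.34) after Myod1. The myogenic list gave adjusted p = 3.58e-16 by camera and adjusted p = 0.098 with an estimated correlation. In the contractile apparatus 18 of 49 fell and 31 did not pass (25 fell adjusted over the list alone), led by Myot (log2 -1.85 ± 0.51) and Csrp3 (log2 -1.62 ± 0.25) of the Z-disc. The contractile list gave adjusted p = 6.31e-15 by camera and adjusted p = 0.127 with an estimated correlation. The abundant sarcomere genes Acta1 (log2 -0.18 ± 0.13) and Mylpf (log2 -0.09 ± 0.15) and creatine kinase Ckm (log2 -0.33 ± 0.16) did not pass. Of the muscle calcium handling and energy metabolism genes, 13 of 34 fell and 21 did not pass (21 fell adjusted over the list alone), with Asph (log2 -1.22 ± 0.23) after Ampd1. The calcium and energy list gave adjusted p = 6.67e-13 by camera and adjusted p = 0.158 with an estimated correlation. The myoblast and reserve cell markers gave 1 rise and 6 falls among 24 genes (2 and 6 adjusted over the list alone), with Spry1 (log2 -1.50 ± 0.20) and Id1 (log2 -1.38 ± 0.27) among the falls. The myoblast marker list gave adjusted p = 0.00265 by camera and adjusted p = 0.10 with an estimated correlation. Without dl312 replicate 1, calls were lost for Myot and Myf6. The calls of Myot, Myf6, Myf5 and Id1 were lost without dl312 replicate 2. Omitting dl520 replicate 1 ended that of Myf6. Myot, Asph, Myf6, Myf5 and Id1 lost their calls without dl520 replicate 2. Under other settings the call of Myot ended (adjusted p = 0.0502 to 0.285 in all).

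Other lists were called in part. In the extracellular matrix and TGF-beta list 15 of 35 fell and 20 did not pass (21 fell adjusted over the list alone), with the ligand Tgfb2 (log2 -1.56 ± 0.27) and Thbs1 (log2 -1.48 ± 0.29) first. The matrix list gave adjusted p = 3.19e-11 by camera and adjusted p = 0.098 with an estimated correlation. Of the immediate early and MAPK feedback genes, 11 of 23 fell and 12 did not pass (11 fell adjusted over the list alone), with Egr3 (log2 -2.05 ± 0.31) and Myc (log2 -1.37 ± 0.33) first. The immediate early list gave adjusted p = 2.38e-06 by camera and adjusted p = 0.098 with an estimated correlation. Falls were fewer among the unfolded protein and integrated stress response genes, where 5 of 27 fell and 22 did not pass (5 fell adjusted over the list alone). The unfolded protein list gave adjusted p = 0.00213 by camera and adjusted p = 0.10 with an estimated correlation. Among heat shock genes and chaperones 4 of 29 fell and 25 did not pass (4 fell adjusted over the list alone), the largest being those of the muscle chaperones Hspb7 (log2 -1.43 ± 0.41) and Hspb8 (log2 -1.23 ± 0.16). The heat shock list gave adjusted p = 0.00129 by camera and adjusted p = 0.166 with an estimated correlation. With quantile normalization the heat shock list no longer passed by camera (median -0.04, adjusted p = 0.399). Of the NF-kappaB targets, cytokines and chemokines, 3 of 20 fell and 17 did not pass (4 fell adjusted over the list alone). The NF-kappaB list gave adjusted p = 0.00851 by camera and adjusted p = 0.465 with an estimated correlation, and adjusted p = 0.0778 by camera with the filter at the 75th percentile. In the muscle atrophy ubiquitin ligase and autophagy list 2 of 18 fell and 16 did not pass (3 fell adjusted over the list alone), the larger fall being that of the atrophy ligase Trim63 (log2 -1.02 ± 0.27). The atrophy list gave adjusted p = 0.0178 by camera and adjusted p = 0.348 with an estimated correlation, and adjusted p = 0.0557 by camera without dl520 replicate 2 and 0.113 with quantile normalization. The p53 targets went both ways, as 3 rose, 2 fell and 24 of 29 did not pass (3 and 2 adjusted over the list alone), with Gadd45a (log2 -1.82 ± 0.41) falling and Dram1 (log2 1.65 ± 0.47) rising, a positive median of 0.12 and a camera direction of down. The p53 list gave adjusted p = 0.855 by camera and adjusted p = 0.909 with an estimated correlation. In the apoptosis list 5 rose, 3 fell and 18 of 26 did not pass (7 and 3 adjusted over the list alone), including the anti-apoptotic Bcl2l1 (log2 -1.15 ± 0.16) and the pro-apoptotic Bcl2l11 (log2 1.15 ± 0.18). The apoptosis list gave adjusted p = 0.38 by camera and adjusted p = 0.47 with an estimated correlation. Single genes passed among the interferon-stimulated genes, Ifi204 (log2 -0.95 ± 0.23) of 36. The interferon list gave adjusted p = 0.317 by camera and adjusted p = 0.771 with an estimated correlation. In ribosome biogenesis it was Nop56 (log2 0.75 ± 0.19) of 31. The ribosome list gave adjusted p = 0.445 by camera and adjusted p = 0.798 with an estimated correlation. Of the cholesterol and fatty acid synthesis genes, 2 of 23 fell and 21 did not pass (2 fell adjusted over the list alone). The cholesterol list gave adjusted p = 0.0746 by camera and adjusted p = 0.624 with an estimated correlation. No gene of the 33 in mitochondrial respiration and the TCA cycle passed in limma, with 1 at an unadjusted p under 0.05, and the median of -0.11 turned to 0.04 with quantile normalization. The mitochondrial list gave adjusted p = 0.00358 by camera and adjusted p = 0.465 with an estimated correlation, and adjusted p = 0.528 by camera with quantile normalization. Leaving out dl312 replicate 1 ended the calls of Thbs1, Gadd45a, Dram1, Ifi204, Myc, Hspb7, Nop56 and Trim63. Without dl312 replicate 2, calls were lost for Dram1, Ifi204, Myc, Hspb7, Nop56 and Trim63. The calls of Dram1 and Ifi204 were lost without dl520 replicate 1. Omitting dl520 replicate 2 ended those of Thbs1, Gadd45a, Dram1, Ifi204, Myc, Hspb7, Nop56 and Trim63. The calls of Myc, Hspb7, Dram1, Ifi204 and Nop56 also ended under other settings (adjusted p = 0.0515 to 0.36 in all).

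Over all 12716 genes, limma called 1853 in this comparison, of which 1177 rose and 676 fell, 742 of them by at least 2-fold. The share that rose was 63.5% and became 46% when each array was centred on its median. The count was 888 without dl312 replicate 1, 731 without dl312 replicate 2 and 509 without dl520 replicate 2, each lone sample being assumed to vary like the other groups. Of the 1177 rises, 253 had a mean dl312 signal below the filter threshold, and of the falls 41 had such a dl520 signal.

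**Figure D1:**
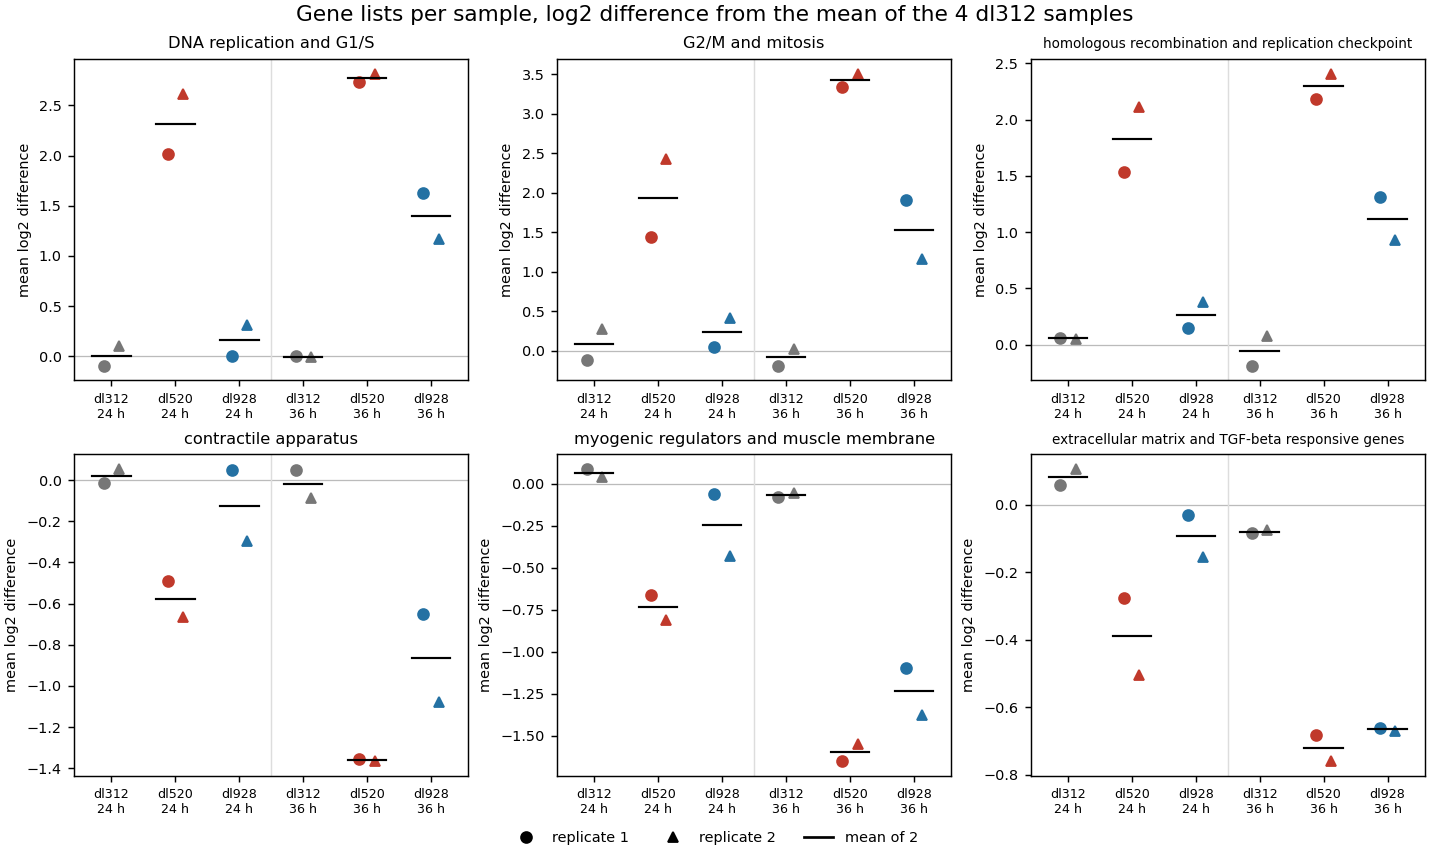
Mean log2 difference of 6 gene lists in each of the 12 samples (points) from the mean of the 4 dl312 samples, with group means as bars. The lists are DNA replication and G1/S, G2/M and mitosis, homologous recombination and replication checkpoint, contractile apparatus, myogenic regulators and muscle membrane, and extracellular matrix.

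At 36 h the comparison of dl520 with dl312 asks the same question 12 h later. The largest rises were in genes of DNA synthesis and of mitosis. They were those of Tk1 (61.4-fold, log2 5.94 ± 0.54), which makes thymidine nucleotides, the spindle checkpoint kinase Bub1 (43-fold, log2 5.42 ± 0.54), the proliferation marker Mki67 (37.8-fold, log2 5.24 ± 0.61), and the centromere gene Cenpi (33-fold, log2 5.04 ± 0.37). After them came Mcm5 (31.6-fold, log2 4.98 ± 0.30), Melk (31.5-fold, log2 4.98 ± 0.44), the survivin gene Birc5 (31.1-fold, log2 4.96 ± 0.44) and Top2a (30.5-fold, log2 4.93 ± 0.40), with adjusted p = 1.53e-06 to 5.45e-05. The dl312 signals of Tk1, Bub1, Mki67, Cenpi and Melk lay below the filter threshold. The largest falls included muscle genes, with Mss51 (13.8-fold, log2 -3.79 ± 0.51), Tceal7 (11.3-fold, log2 -3.50 ± 0.34), the actin-binding Abra (11.1-fold, log2 -3.48 ± 0.40), and the acetylcholine receptor subunit Chrne (11-fold, log2 -3.46 ± 0.46). The others were Cfap52 (10.7-fold, log2 -3.42 ± 0.46), the muscle chaperone Hspb7 (9.9-fold, log2 -3.31 ± 0.41), Lmod3 (9.58-fold, log2 -3.26 ± 0.30), which nucleates thin filaments, and Bex1 (9.4-fold, log2 -3.23 ± 0.26), at adjusted p = 4.98e-06 to 1.58e-04. Abra, Chrne and Cfap52 lay below the threshold in dl520.

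Among DNA replication and G1/S genes, 49 of 50 rose and 1 did not pass (49 rose adjusted over the list alone), at a median of 2.55. Camera on the replication list gave adjusted p = 2.44e-32 and adjusted p = 0.124 with an estimated correlation. For G2/M and mitosis, 55 of 57 rose and 2 did not pass (55 rose adjusted over the list alone), at a median of 3.69, with the cyclin A2 gene Ccna2 (log2 3.69 ± 0.36) and Cdk1 (log2 4.34 ± 0.46) among them. Camera on the mitosis list gave adjusted p = 6.97e-34 and adjusted p = 0.124 with an estimated correlation. Homologous recombination and checkpoint genes followed, where 29 of 30 rose and 1 did not pass (29 rose adjusted over the list alone), with Rad51ap1 (log2 4.82 ± 0.39) and Timeless (log2 4.55 ± 0.31) first. Camera on the recombination list gave adjusted p = 2.37e-18 and adjusted p = 0.124 with an estimated correlation. In chromatin and DNA methylation 22 of 27 rose and 5 did not pass (23 rose adjusted over the list alone), with Hmgb2 (log2 4.36 ± 0.37) and the condensin subunit Ncapg (log2 3.91 ± 0.40) first. Camera on the chromatin list gave adjusted p = 6.43e-12 and adjusted p = 0.127 with an estimated correlation. In the pocket protein, E2F, cyclin and CDK list 14 rose, 5 fell and 7 of 26 did not pass (15 and 5 adjusted over the list alone). Camera on the E2F and CDK list gave adjusted p = 0.00773 and adjusted p = 0.225 with an estimated correlation. It held rises of E2f1 (log2 2.67 ± 0.29), E2f7 (log2 3.63 ± 0.27), Rbl1 (log2 2.34 ± 0.21) and the p130 gene Rbl2 (log2 0.87 ± 0.15) and falls of Ccnd1 (log2 -1.53 ± 0.21), Ccnd3 (log2 -1.01 ± 0.10) and the CDK inhibitor Cdkn1a (log2 -0.52 ± 0.13), while Rb1 (log2 -0.11 ± 0.17) did not pass. At least 1 other setting ended the call of Cdkn1a (adjusted p = 0.066).

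In the 3 muscle lists every member that passed at 36 h with dl520 fell. Of the contractile apparatus, 42 of 49 fell and 7 did not pass (45 fell adjusted over the list alone), with Tcap (log2 -2.95 ± 0.35) of the Z-disc and Myot (log2 -2.77 ± 0.51) after Lmod3. Camera on the contractile list gave adjusted p = 1.77e-24 and adjusted p = 0.124 with an estimated correlation. Fast myosin Myh4 (log2 -2.48 ± 0.56), troponin Tnnt3 (log2 -0.80 ± 0.13) and skeletal actin Acta1 (log2 -0.46 ± 0.13) were in this list, and Mylpf (log2 -0.34 ± 0.15) did not pass. In calcium handling and energy metabolism 27 of 34 fell and 7 did not pass (28 fell adjusted over the list alone), with Ampd1 (log2 -2.85 ± 0.53) and the calcium channel subunit Cacng1 (log2 -2.69 ± 0.16) first. Camera on the calcium and energy list gave adjusted p = 7.98e-18 and adjusted p = 0.124 with an estimated correlation. Of the myogenic regulators and muscle membrane genes, 26 of 30 fell and 4 did not pass (27 fell adjusted over the list alone), among them Myod1 (log2 -3.16 ± 0.29), Myog (log2 -2.57 ± 0.17) and the receptor subunit Chrnd (log2 -2.84 ± 0.27). Camera on the myogenic list gave adjusted p = 1.39e-19 and adjusted p = 0.124 with an estimated correlation. Acta1 lost its call without dl312 replicate 1 or dl520 replicate 1. Without dl520 replicate 2, the call of Myh4 was lost. Other settings ended the call of Acta1 (adjusted p = 0.0542 to 0.187 in all).

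Extracellular matrix and TGF-beta genes mostly fell, as 1 rose, 23 fell and 11 of 35 did not pass (1 and 23 adjusted over the list alone), with Tgfb3 (log2 -2.02 ± 0.18) and Tgfb2 (log2 -1.66 ± 0.27) first and the collagens Col3a1 (log2 -1.56 ± 0.28) and Col1a1 (log2 -1.02 ± 0.12) among them. Camera on the matrix list gave adjusted p = 1.07e-09 and adjusted p = 0.124 with an estimated correlation. Of the immediate early and MAPK feedback genes, 1 rose, 7 fell and 15 of 23 did not pass (1 and 7 adjusted over the list alone), with falls of Egr3 (log2 -3.07 ± 0.31) and Myc (log2 -2.22 ± 0.33) and a rise of the stress-induced Atf3 (log2 1.81 ± 0.32). Camera on the immediate early list gave adjusted p = 0.00172 and adjusted p = 0.138 with an estimated correlation. For heat shock genes and chaperones, 1 rose, 9 fell and 19 of 29 did not pass (1 and 9 adjusted over the list alone), led by Hspb7 and Hspb8 (log2 -2.19 ± 0.16), and the median of -0.20 turned to 0.0016 with quantile normalization. Camera on the heat shock list gave adjusted p = 0.00198 and adjusted p = 0.19 with an estimated correlation, and adjusted p = 0.722 by camera with quantile normalization. In mitochondrial respiration and the TCA cycle 2 rose, 15 fell and 16 of 33 did not pass (2 and 18 adjusted over the list alone), with Idh2 (log2 0.99 ± 0.19) up and Mdh1 (log2 -0.79 ± 0.15) down. Camera on the mitochondrial list gave adjusted p = 2.24e-06 and adjusted p = 0.238 with an estimated correlation, and adjusted p = 0.321 by camera with quantile normalization. The p53 targets were mixed, as 9 rose, 4 fell and 16 of 29 did not pass (11 and 5 adjusted over the list alone), with Gadd45a (log2 -2.41 ± 0.41) down and Pidd1 (log2 1.85 ± 0.23) up. Camera on the p53 list gave adjusted p = 0.43 and adjusted p = 0.639 with an estimated correlation.

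NF-kappaB targets, cytokines and chemokines differed between the 2 dl312 samples at 36 h, as replicate 1 exceeded replicate 2 by a list mean of 1.39 (log2), and this bears on the comparison with dl520. In that list 1 rose, 7 fell and 12 of 20 did not pass (1 and 7 adjusted over the list alone), with Ccl5 (log2 -2.26 ± 0.47) and Ccl7 (log2 -2.13 ± 0.74) down and Cxcl12 (log2 1.67 ± 0.32) up. Camera on the NF-kappaB list gave adjusted p = 4.42e-04 and adjusted p = 0.285 with an estimated correlation. Of the interferon-stimulated genes, 4 rose, 2 fell and 30 of 36 did not pass (1 and 1 adjusted over the list alone), with Ifit2 (log2 1.35 ± 0.48) and Ifi204 (log2 -1.08 ± 0.23) as the largest, a median of 0.10 and a camera direction of down. Camera on the interferon list gave adjusted p = 0.972 and adjusted p = 0.99 with an estimated correlation. The calls of Ifit2 and Ccl7 were lost without dl312 replicate 1. Omitting dl312 replicate 2 ended that of Ifit2. Ifit2 and Ccl7 lost their calls without dl520 replicate 1. Leaving out dl520 replicate 2 ended the calls of Ifit2 and Ccl7. Under other settings the calls of Ccl7 and Ifit2 ended (adjusted p = 0.051 to 0.378 in all).

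Over all genes, limma called 4068 at 36 h, of which 2326 rose and 1742 fell, 1510 by at least 2-fold. The share that rose was 57.2% and became 36.4% with median centring, as the median change of all genes was 0.11 as deposited and -0.08 with centring. Of the genes called at 24 h, 1063 of the 1177 that rose also rose at 36 h (215 if the calls were independent) and 622 of the 676 that fell also fell (92.6 if independent). A mean dl312 signal below the filter threshold lay behind 395 of the 2326 rises, and such a dl520 signal behind 146 of the 1742 falls. Without the 2 samples with high chemokine genes, described with the time comparisons, the count was 3326.

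**Figure D2:**
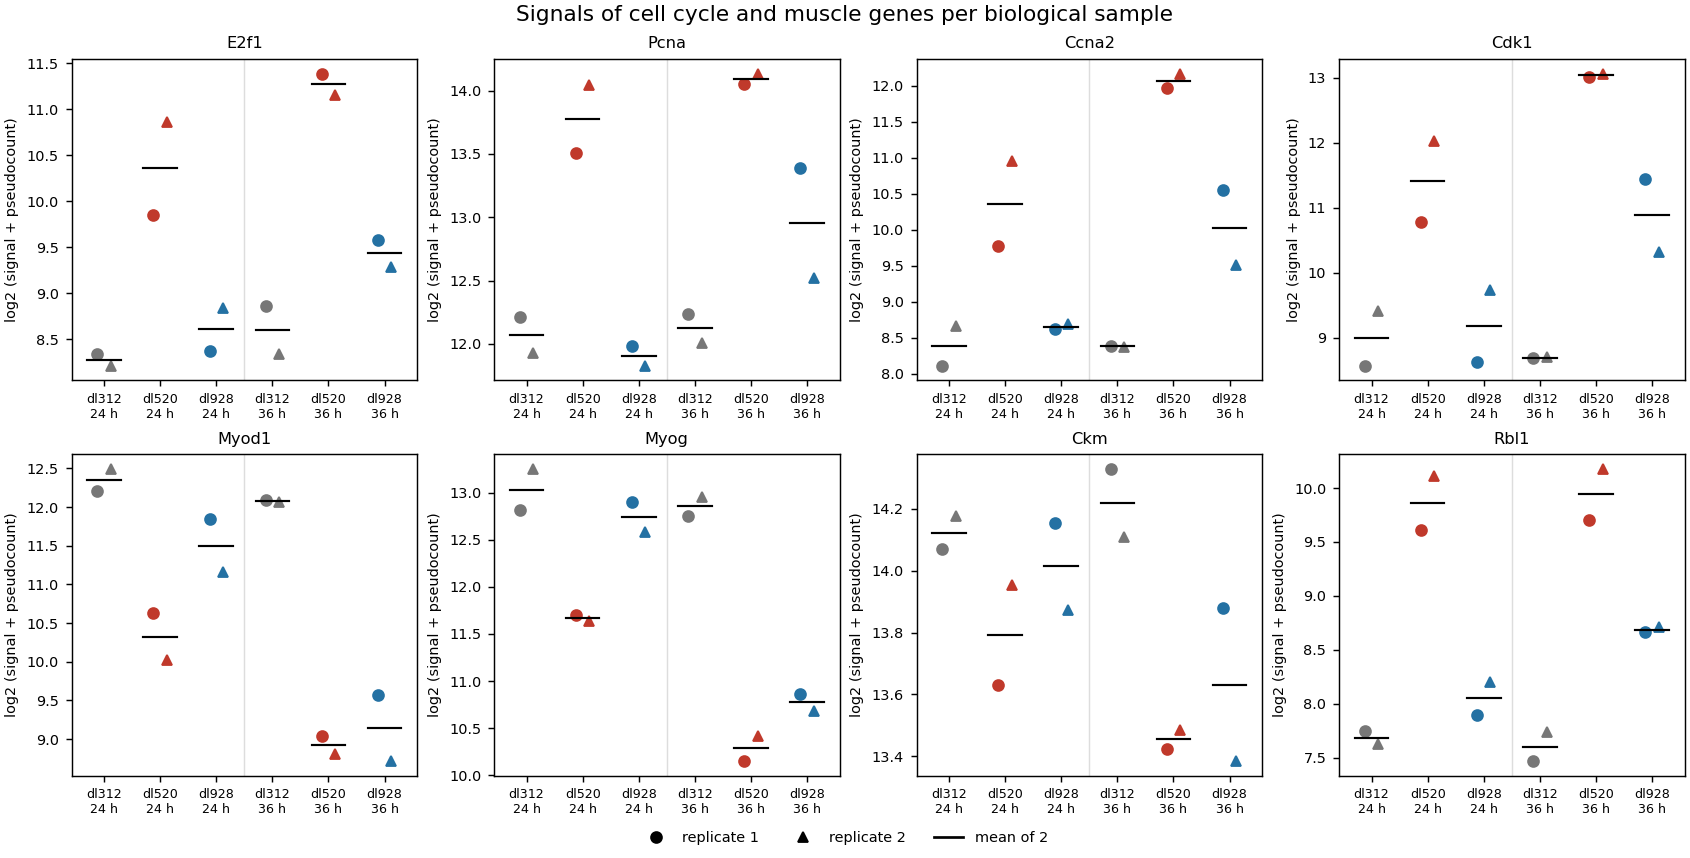
Log2 signal of E2f1, Pcna, Ccna2, Cdk1, Myod1, Myog, Ckm and Rbl1 in each of the 12 samples (points), by virus and time, with group means as bars.

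The comparison of dl928 with dl312 at 24 h asks whether the mutant E1A had acted by then. No gene passed in limma, with 905 of 12716 genes at an unadjusted p under 0.05 (636 by chance) and a smallest adjusted p of 0.321. The genes at an unadjusted p under 0.05 numbered 264 without dl928 replicate 2, 547 without dl312 replicate 1 and 1372 without dl928 replicate 1, below and above the number by chance. Among the 54 members of the lists with an unadjusted p under 0.05, of 645 measured, none passed over all genes, and adjusted over the list alone 5 myoblast and reserve cell markers fell, Cxcr4 (log2 -1.27 ± 0.34) and Id1 (log2 -1.06 ± 0.27) having the largest values. The replication genes Mcm5 (log2 0.58 ± 0.30) and Cdc6 (log2 0.58 ± 0.33) and the cyclins Ccne1 (log2 0.29 ± 0.41) and Ccna2 (log2 0.27 ± 0.36) did not pass, nor did Myod1 (log2 -0.85 ± 0.29), Myog (log2 -0.29 ± 0.17) and Ccl5 (log2 -1.89 ± 0.47).

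Camera nevertheless placed several lists below the other genes, each by a small median. The myogenic regulators and muscle membrane genes had a median of -0.24. For the myogenic list camera gave adjusted p = 6.17e-10 and adjusted p = 0.176 with an estimated correlation. For calcium handling and energy metabolism the median was -0.18, and for immediate early genes -0.23. For the calcium and energy list camera gave adjusted p = 2.00e-09 and adjusted p = 0.425 with an estimated correlation. For the immediate early list camera gave adjusted p = 1.38e-06 and adjusted p = 0.157 with an estimated correlation. For myoblast markers the median was -0.17. For the myoblast marker list camera gave adjusted p = 1.77e-06 and adjusted p = 0.0714 with an estimated correlation. DNA replication and G1/S stood at 0.14 and G2/M and mitosis at 0.21. For the replication list camera gave adjusted p = 0.167 and adjusted p = 0.925 with an estimated correlation. For the mitosis list camera gave adjusted p = 0.499 and adjusted p = 0.925 with an estimated correlation. Without dl928 replicate 1 the replication median was 0.31 (adjusted p = 0.00537 by camera) and the mitosis median 0.40 (adjusted p = 0.047). Without dl312 replicate 2 mitosis stood at 0.41 (adjusted p = 0.0129), and without _x_at and _s_at probe sets replication stood at 0.20 (adjusted p = 0.0498). Homologous recombination and the replication checkpoint had a median of 0.23. For the recombination list camera gave adjusted p = 0.0616 and adjusted p = 0.925 with an estimated correlation. It passed by camera under 9 alternatives (adjusted p = 0.0257 to 0.0473), among them a replicate block (adjusted p = 0.0441), median centring and leaving out dl312 replicate 1 or dl928 replicate 1. Without dl928 replicate 2, calcium handling no longer passed by camera (median -0.03, adjusted p = 0.083), and the contractile median of -0.05 became 0.049. For the contractile list camera gave adjusted p = 0.00117 and adjusted p = 0.743 with an estimated correlation. The contractile list also no longer passed without dl312 replicate 2 (adjusted p = 0.172) or on technical arrays B alone (adjusted p = 0.0561). The simulated recovery, with 200 genes changed, does not carry over here, where no gene passed.

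At 36 h the comparison of dl928 with dl312 showed large changes. Rises were led by Tk1 (11.8-fold, log2 3.56 ± 0.54), Ccne2 (11-fold, log2 3.45 ± 0.32), Ercc6l (9.92-fold, log2 3.31 ± 0.38) and Mcm5 (9.89-fold, log2 3.31 ± 0.30). The next were Bub1 (9.86-fold, log2 3.30 ± 0.54), Hmgb2 (9.62-fold, log2 3.27 ± 0.37), the PCNA-associated Pclaf (8.47-fold, log2 3.08 ± 0.43) and Bub1b (8.44-fold, log2 3.08 ± 0.38), with adjusted p = 1.20e-04 to 0.00172. Ccne2 went from a signal of 149.8 ± 36.7 in dl312 to 1999 ± 757. In dl312 the signals of Tk1, Ercc6l, Bub1 and Bub1b lay below the filter threshold. The largest falls were those of Mss51 (10.9-fold, log2 -3.45 ± 0.51), the immediate early gene Egr3 (9.62-fold, log2 -3.27 ± 0.31), Ly6g2 (8.32-fold, log2 -3.06 ± 0.50), and Myod1 (7.66-fold, log2 -2.94 ± 0.29). They were followed by Cfap52 (7.61-fold, log2 -2.93 ± 0.46), A4galt (7.56-fold, log2 -2.92 ± 0.64), Chrne (7.38-fold, log2 -2.88 ± 0.46) and Smim5 (7.05-fold, log2 -2.82 ± 0.24), at adjusted p = 9.76e-05 to 0.00835. With dl928 Ly6g2, Cfap52, A4galt and Chrne lay below the threshold. Without dl312 replicate 1, the call of A4galt was lost. The call of A4galt also ended under other settings (adjusted p = 0.0763 to 0.134 in all).

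Of the DNA replication and G1/S genes, 37 of 50 rose and 13 did not pass (42 rose adjusted over the list alone), with a median of 1.26 and with Gins2 (log2 3.07 ± 0.32) of the helicase complex after Tk1, Ccne2 and Mcm5. The replication genes gave adjusted p = 3.01e-19 by camera and adjusted p = 0.217 with an estimated correlation. In G2/M and mitosis 47 rose, 1 fell and 9 of 57 did not pass (52 and 1 adjusted over the list alone), with Melk (log2 2.95 ± 0.44) and Top2a (log2 2.87 ± 0.40) rising. The mitosis genes gave adjusted p = 1.88e-18 by camera and adjusted p = 0.234 with an estimated correlation. Homologous recombination and checkpoint genes rose, as 22 of 30 rose and 8 did not pass (23 rose adjusted over the list alone), with Rad51ap1 (log2 2.79 ± 0.39), Rad54l (log2 2.31 ± 0.36) and Brca1 (log2 2.05 ± 0.30) first. The recombination genes gave adjusted p = 7.04e-11 by camera and adjusted p = 0.222 with an estimated correlation. The pocket protein, E2F, cyclin and CDK list was divided, as 9 rose, 4 fell and 13 of 26 did not pass (10 and 4 adjusted over the list alone), with Ccne1 (log2 2.24 ± 0.41), E2f7 (log2 2.14 ± 0.27) and Rbl1 (log2 1.08 ± 0.21) up and E2f2 (log2 -2.16 ± 0.17), Ccnd1 (log2 -1.55 ± 0.21), Ccnd3 (log2 -0.86 ± 0.10) and Cdkn1a (log2 -0.85 ± 0.13) down. The E2F and CDK genes gave adjusted p = 0.832 by camera and adjusted p = 0.943 with an estimated correlation. E2f1 (log2 0.83 ± 0.29), Rb1 (log2 -0.28 ± 0.17) and the nucleotide synthesis genes Rrm2 (log2 0.16 ± 0.22) and Tyms (log2 0.23 ± 0.26) did not pass. At least 1 other setting ended the calls of Rbl1 and Ccnd3 (adjusted p = 0.0535 to 0.0624).

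In the 3 muscle lists 73 of 113 members fell with dl928 at 36 h. Of the contractile apparatus, 1 rose, 28 fell and 20 of 49 did not pass (1 and 32 adjusted over the list alone), with Lmod3 (log2 -2.47 ± 0.30) and Ldb3 (log2 -2.08 ± 0.29) after Myot (log2 -2.5 ± 0.51). The contractile genes gave adjusted p = 2.46e-18 by camera and adjusted p = 0.129 with an estimated correlation. In calcium handling and energy metabolism 25 of 34 fell and 9 did not pass (28 fell adjusted over the list alone), with Ampd1 (log2 -2.75 ± 0.53) and mitochondrial creatine kinase Ckmt2 (log2 -2.13 ± 0.32) first. The calcium and energy genes gave adjusted p = 3.71e-20 by camera and adjusted p = 0.129 with an estimated correlation. Of the myogenic regulators and muscle membrane genes, 20 of 30 fell and 10 did not pass (26 fell adjusted over the list alone), with Myf6 (log2 -2.43 ± 0.44), Tead4 (log2 -2.11 ± 0.24) and Myog (log2 -2.08 ± 0.17). The myogenic genes gave adjusted p = 3.71e-20 by camera and adjusted p = 0.0783 with an estimated correlation. Skeletal actin Acta1 (log2 -0.06 ± 0.13), Mylpf (log2 0.01 ± 0.15), Myh4 (log2 -1.43 ± 0.56) and Mef2c (log2 -0.78 ± 0.42) did not pass. For myoblast and reserve cell markers, 6 of 24 fell and 18 did not pass (6 fell adjusted over the list alone), with Myf5 (log2 -1.98 ± 0.34) and Cxcr4 (log2 -1.86 ± 0.34) first. The myoblast marker genes gave adjusted p = 1.78e-04 by camera and adjusted p = 0.0783 with an estimated correlation. The extracellular matrix and TGF-beta list gave 21 falls among 35 genes (22 adjusted over the list alone), with Tgfb3 (log2 -1.66 ± 0.18) and Col3a1 (log2 -1.42 ± 0.28) first. The matrix genes gave adjusted p = 2.06e-12 by camera and adjusted p = 0.0783 with an estimated correlation. The call of Myot was lost without dl928 replicate 2 (adjusted p = 0.055).

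Of the immediate early and MAPK feedback genes, 2 rose, 7 fell and 14 of 23 did not pass (2 and 11 adjusted over the list alone), with Dusp6 (log2 -1.77 ± 0.27) after Egr3 and Atf3 (log2 1.72 ± 0.32) up. The immediate early genes gave adjusted p = 2.58e-04 by camera and adjusted p = 0.142 with an estimated correlation. The p53 targets fell more often than they rose, as 2 rose, 7 fell and 20 of 29 did not pass (2 and 8 adjusted over the list alone), with Gadd45a (log2 -2.51 ± 0.41) and Eda2r (log2 -1.56 ± 0.26) first. The p53 genes gave adjusted p = 0.00534 by camera and adjusted p = 0.222 with an estimated correlation. By camera they no longer passed without dl312 replicate 2 (adjusted p = 0.0689) or dl928 replicate 2 (adjusted p = 0.0511). In mitochondrial respiration 1 rose, 7 fell and 25 of 33 did not pass (1 and 7 adjusted over the list alone), the median of -0.14 turning to 0.0059 with quantile normalization. The mitochondrial genes gave adjusted p = 1.65e-04 by camera and adjusted p = 0.364 with an estimated correlation, and adjusted p = 0.055 by camera without dl312 replicate 1 and 0.625 with quantile normalization.

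Replicate 1 of both dl312 and dl928 at 36 h had high chemokine genes, which bears on the interferon and NF-kappaB lists here. Of the interferon-stimulated genes, 4 of 36 rose (1 adjusted over the list alone), Ifit1 (log2 1.78 ± 0.51), the double-stranded RNA kinase Eif2ak2 (log2 1.12 ± 0.20), Irf7 (log2 1.07 ± 0.29) and Irf9 (log2 0.79 ± 0.23). The interferon genes gave adjusted p = 0.0856 by camera and adjusted p = 0.674 with an estimated correlation, and adjusted p = 0.0047 by camera without dl312 replicate 1, 4.75e-05 without dl928 replicate 2, 0.0385 without the filter, 0.0344 with median centring and 0.0486 with technical arrays A. In NF-kappaB targets, cytokines and chemokines 1 rose, 3 fell and 16 of 20 did not pass (1 and 3 adjusted over the list alone), with Cxcl12 (log2 1.53 ± 0.32) up and Ptgs2 (log2 -1.14 ± 0.29) down. The NF-kappaB genes gave adjusted p = 0.105 by camera and adjusted p = 0.674 with an estimated correlation, and adjusted p = 1.82e-04 by camera without dl928 replicate 1, 9.85e-04 without dl312 replicate 2, 0.0400 with technical arrays A and 0.0427 without both samples with high chemokine genes. Omitting dl312 replicate 1 ended the call of Irf9. Ifit1, Irf7, Irf9 and Ptgs2 lost their calls without dl312 replicate 2. Leaving out dl928 replicate 1 ended the calls of Ifit1, Irf7 and Irf9. Without dl928 replicate 2, calls were lost for Cxcl12 and Ptgs2. Other settings ended the calls of Ifit1, Irf7, Irf9 and Ptgs2 (adjusted p = 0.0508 to 0.211 in all).

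Over all genes, limma called 2578 with dl928 at 36 h, of which 1435 rose and 1143 fell, 857 by at least 2-fold. The share that rose was 55.7% and became 34.7% with median centring and 47.9% with quantile normalization, the median change of all genes being 0.11 as deposited and -0.02 with centring. The count was 1635 without dl312 replicate 1, 1340 without dl928 replicate 2, and 1606 without both samples with high chemokine genes. A mean dl312 signal below the filter threshold lay behind 218 of the 1435 rises, and such a dl928 signal behind 122 of the 1143 falls.

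The direct comparison of dl520 with dl928 at 24 h asks where 12S E1A and its mutant differed. Replication genes were higher with dl520, led by Timeless (21.2-fold, log2 4.41 ± 0.31), Ccne2 (20-fold, log2 4.32 ± 0.32), Mcm5 (16.5-fold, log2 4.05 ± 0.30), and Uhrf1 (14.1-fold, log2 3.81 ± 0.29). The next were the licensing factor Cdt1 (13.8-fold, log2 3.78 ± 0.21), Ercc6l (13.2-fold, log2 3.72 ± 0.38), Mcm3 (12.7-fold, log2 3.67 ± 0.25) and Tcf19 (12-fold, log2 3.59 ± 0.33), with adjusted p = 6.10e-06 to 1.78e-04. The signal of Cdt1 was 402 ± 104 with dl928 and 5929.9 ± 1519 with dl520, and those of Timeless and Ercc6l with dl928 lay below the filter threshold. Lower with dl520 were the kinase gene Csnk1d (2.63-fold, log2 -1.40 ± 0.26), Tas1r2 (2.54-fold, log2 -1.35 ± 0.34), Smim5 (2.5-fold, log2 -1.32 ± 0.24) and Nmrk2 (2.49-fold, log2 -1.32 ± 0.25), which makes NAD in muscle. The others were Fam107a (2.43-fold, log2 -1.28 ± 0.26), Myod1 (2.26-fold, log2 -1.18 ± 0.29), the muscle membrane anchor Ank1 (2.22-fold, log2 -1.15 ± 0.21) and Bex1 (2.22-fold, log2 -1.15 ± 0.26), at adjusted p = 0.00694 to 0.0429. Tas1r2 and Nmrk2 lay below the threshold with dl520. The calls of Tas1r2 and Bex1 were lost without dl520 replicate 1. Omitting dl520 replicate 2 ended those of Csnk1d, Tas1r2, Smim5, Nmrk2, Fam107a, Myod1, Ank1 and Bex1. Tas1r2, Smim5, Nmrk2, Fam107a, Myod1, Ank1 and Bex1 lost their calls without dl928 replicate 1. Leaving out dl928 replicate 2 ended the calls of Tas1r2 and Bex1. Under other settings the calls of Csnk1d, Tas1r2, Smim5, Nmrk2, Fam107a, Myod1, Ank1 and Bex1 ended (adjusted p = 0.0502 to 0.687 in all).

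Of the DNA replication and G1/S genes, 46 of 50 were higher with dl520 and 4 did not pass (48 higher adjusted over the list alone), at a median of 1.98. By camera the replication list gave adjusted p = 1.56e-69 and adjusted p = 0.112 with an estimated correlation. The G2/M and mitosis list gave 45 of 57 higher (53 adjusted over the list alone), with Sgo1 (log2 3.37 ± 0.38) and Melk (log2 3.28 ± 0.44) first. By camera the mitosis list gave adjusted p = 6.10e-42 and adjusted p = 0.112 with an estimated correlation. In homologous recombination and the replication checkpoint 16 of 30 were higher (27 adjusted over the list alone), including Clspn (log2 3.16 ± 0.34) and Brca1 (log2 2.83 ± 0.30). By camera the recombination list gave adjusted p = 2.47e-29 and adjusted p = 0.112 with an estimated correlation. In the pocket protein, E2F, cyclin and CDK list 10 were higher and 1 lower of 26 (13 and 2 adjusted over the list alone), Ccne1 (log2 2.79 ± 0.41), E2f7 (log2 3.21 ± 0.27), Rbl1 (log2 1.81 ± 0.21) and E2f1 (log2 1.75 ± 0.29) among the higher. By camera the E2F and CDK list gave adjusted p = 1.58e-05 and adjusted p = 0.112 with an estimated correlation. Among muscle genes, 5 of 30 myogenic regulators and membrane genes were lower (11 adjusted over the list alone), Myog (log2 -1.07 ± 0.17) and the caveolin 3 gene Cav3 (log2 -0.88 ± 0.17) after Myod1. By camera the myogenic list gave adjusted p = 4.69e-11 and adjusted p = 0.112 with an estimated correlation. Also lower were 4 of 49 contractile genes (11 adjusted over the list alone), with Csrp3 (log2 -1.0 ± 0.25) and Xirp1 (log2 -0.96 ± 0.22) first. By camera the contractile list gave adjusted p = 1.83e-14 and adjusted p = 0.128 with an estimated correlation. Without dl520 replicate 2, calls were lost for Csrp3, Xirp1, Myog, Cav3 and E2f1. The calls of Csrp3, Xirp1, Myog, Cav3 and E2f1 were lost without dl928 replicate 1. Omitting dl928 replicate 2 ended that of Cav3. The calls of Csrp3 and Xirp1 also ended under other settings (adjusted p = 0.0511 to 0.39 in all).

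Over all genes, limma called 562 at 24 h, 475 higher and 87 lower with dl520, 329 by at least 2-fold. The share higher was 84.5% and became 71% with median centring. The count was 123 without dl520 replicate 2 and 149 without dl928 replicate 1.

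At 36 h the largest differences between dl520 and dl928 included genes of DNA replication and of mitosis. Higher with dl520 were Pole (15-fold, log2 3.91 ± 0.36) of DNA polymerase epsilon, the cyclin B2 gene Ccnb2 (7.65-fold, log2 2.93 ± 0.32), Gtse1 (7.09-fold, log2 2.83 ± 0.37) and the centromeric histone Cenpa (6.63-fold, log2 2.73 ± 0.27). The next were Cdca3 (6.61-fold, log2 2.72 ± 0.34), Mki67 (6.47-fold, log2 2.69 ± 0.61), Timeless (5.84-fold, log2 2.55 ± 0.31) and Nusap1 (5.73-fold, log2 2.52 ± 0.40) of the spindle, with adjusted p = 9.19e-04 to 0.0256. Ccnb2 stood at 568 ± 156 with dl928 and 4475 ± 420.4 with dl520, and Pole at 31.1 ± 10.9, below the filter threshold, and 899.8 ± 199.9. Lower with dl520 were Ccl5 (4.14-fold, log2 -2.05 ± 0.47), the cytochrome oxidase assembly gene Sco2 (3.82-fold, log2 -1.93 ± 0.28), the nuclear RNA Neat1 (2.92-fold, log2 -1.55 ± 0.34), and Gpatch3 (2.68-fold, log2 -1.42 ± 0.36). The others were adhesion molecule Vcam1 (2.62-fold, log2 -1.39 ± 0.34), Tcp11l2 (2.59-fold, log2 -1.37 ± 0.22), Xylt2 (2.41-fold, log2 -1.27 ± 0.29) and Parp3 (2.35-fold, log2 -1.23 ± 0.16), at adjusted p = 0.00228 to 0.0406. With dl520 Ccl5, Gpatch3 and Xylt2 lay below the threshold. Mki67, Ccl5, Neat1, Gpatch3, Vcam1 and Xylt2 lost their calls without dl520 replicate 1. Leaving out dl520 replicate 2 ended the calls of Mki67, Ccl5, Neat1, Gpatch3, Vcam1, Tcp11l2 and Xylt2. Without dl928 replicate 1, calls were lost for Ccl5, Neat1 and Vcam1. The calls of Mki67, Ccl5, Neat1, Gpatch3 and Xylt2 were lost without dl928 replicate 2. At least 1 other setting ended the calls of Mki67, Ccl5, Neat1, Gpatch3, Vcam1 and Xylt2 (adjusted p = 0.0509 to 0.65 in all).

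In DNA replication and G1/S, 42 of 50 were higher with dl520 (48 adjusted over the list alone), at a median of 1.30. The replication list, by camera, gave adjusted p = 4.74e-43 and adjusted p = 0.102 with an estimated correlation. Of the G2/M and mitosis genes 51 of 57 were higher (56 adjusted over the list alone), at 2.03. The mitosis list, by camera, gave adjusted p = 1.53e-48 and adjusted p = 0.107 with an estimated correlation. Chromatin gave 10 of 27, led by the condensin subunit Ncapd2 (log2 2.35 ± 0.30) (14 adjusted over the list alone). The chromatin list, by camera, gave adjusted p = 2.53e-11 and adjusted p = 0.169 with an estimated correlation. The pocket protein, E2F, cyclin and CDK list gave 9 of 26, including E2f1 (log2 1.84 ± 0.29) and E2f2 (log2 1.56 ± 0.17) (13 adjusted over the list alone). The E2F and CDK list, by camera, gave adjusted p = 3.89e-08 and adjusted p = 0.102 with an estimated correlation. The p53 targets were higher with dl520 in 7 of 29 cases (11 adjusted over the list alone), with the pro-apoptotic Apaf1 (log2 1.28 ± 0.21) and Pmaip1 (log2 1.15 ± 0.23) first. The p53 list, by camera, gave adjusted p = 1.37e-07 and adjusted p = 0.102 with an estimated correlation. Lower with dl520 were 10 of 49 contractile genes (25 adjusted over the list alone), with perinatal myosin Myh8 (log2 -0.99 ± 0.23) first. The contractile list, by camera, gave adjusted p = 3.38e-16 and adjusted p = 0.133 with an estimated correlation. Also lower were 8 of 30 myogenic regulators and membrane genes (10 adjusted over the list alone), with Chrnd (log2 -1.12 ± 0.27) first, and 7 of 29 heat shock genes and chaperones (10 adjusted over the list alone), with Hspa1b (log2 -0.93 ± 0.15) first. The myogenic list, by camera, gave adjusted p = 5.18e-07 and adjusted p = 0.176 with an estimated correlation. The heat shock list, by camera, gave adjusted p = 9.49e-08 and adjusted p = 0.102 with an estimated correlation. Myod1 (log2 -0.22 ± 0.29) and Myog (log2 -0.49 ± 0.17) did not pass. Omitting dl520 replicate 1 ended the call of Chrnd. Myh8, Apaf1 and Pmaip1 lost their calls without dl520 replicate 2. Leaving out dl928 replicate 1 ended the calls of Myh8 and Chrnd. Without dl928 replicate 2, calls were lost for Myh8, Chrnd, Apaf1 and Pmaip1. Other settings ended the calls of Myh8 and Chrnd (adjusted p = 0.0505 to 0.273 in all).

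The chemokine genes were high in dl928 replicate 1 at 36 h, by a list mean of 1.37 (log2) over replicate 2. The NF-kappaB, cytokine and chemokine list had 3 of 20 lower with dl520 (3 adjusted over the list alone), Ccl5, Vcam1 and Birc3 (log2 -0.92 ± 0.24). The NF-kappaB list, by camera, gave adjusted p = 4.16e-04 and adjusted p = 0.421 with an estimated correlation. It no longer passed by camera without that sample (adjusted p = 0.388). The call of Birc3 was lost without replicate 1 or replicate 2 of dl520 or of dl928. Under other settings the call of Birc3 ended (adjusted p = 0.0554 to 0.70 in all).

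Over all genes, limma called 655 at 36 h, 492 higher and 163 lower with dl520, 328 by at least 2-fold. The share higher was 75.1% and became 65% with median centring. The count was 171 without dl520 replicate 1, 171 without dl520 replicate 2 and 175 without dl928 replicate 2.

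The shared and the separate parts of both responses were counted gene by gene with the direct comparison. Of the 1177 genes that rose with dl520 at 24 h, 459 (39%) rose further than with dl928 by that test, and of the 676 that fell, 82 (12.1%) fell further. At 36 h the counts were 456 of 2326 rises (19.6%) and 120 of 1742 falls (6.89%), and 4 falls were less deep than with dl928. Both tests used the same dl520 samples, so that the choice of genes called with dl520 favours a further change with dl520. At 36 h 1125 genes rose with both viruses against dl312 and 974 fell with both, against 262 and 157 if the calls were independent, values that leave out the shared dl312 samples. In 100 simulations of unchanged groups against shared dl312 samples no gene was called with both. Groups without any change give almost no calls after adjustment, so this does not measure the effect of the shared samples on the overlap. As many top genes as were called with each virus shared a mean of 696.5 rises (at most 734) and 488.7 falls (at most 518) in these simulations. Part of the overlap may come from the shared dl312 samples. Across all genes the log2 changes of both viruses correlated at r = 0.6 at 24 h and r = 0.85 at 36 h, where the shared dl312 samples alone gave r = 0.5 in 100 simulations at each time. The covariance was 0.0854 at 24 h and 0.371 at 36 h, against 0.0246 in the simulations.

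**Figure D3:**
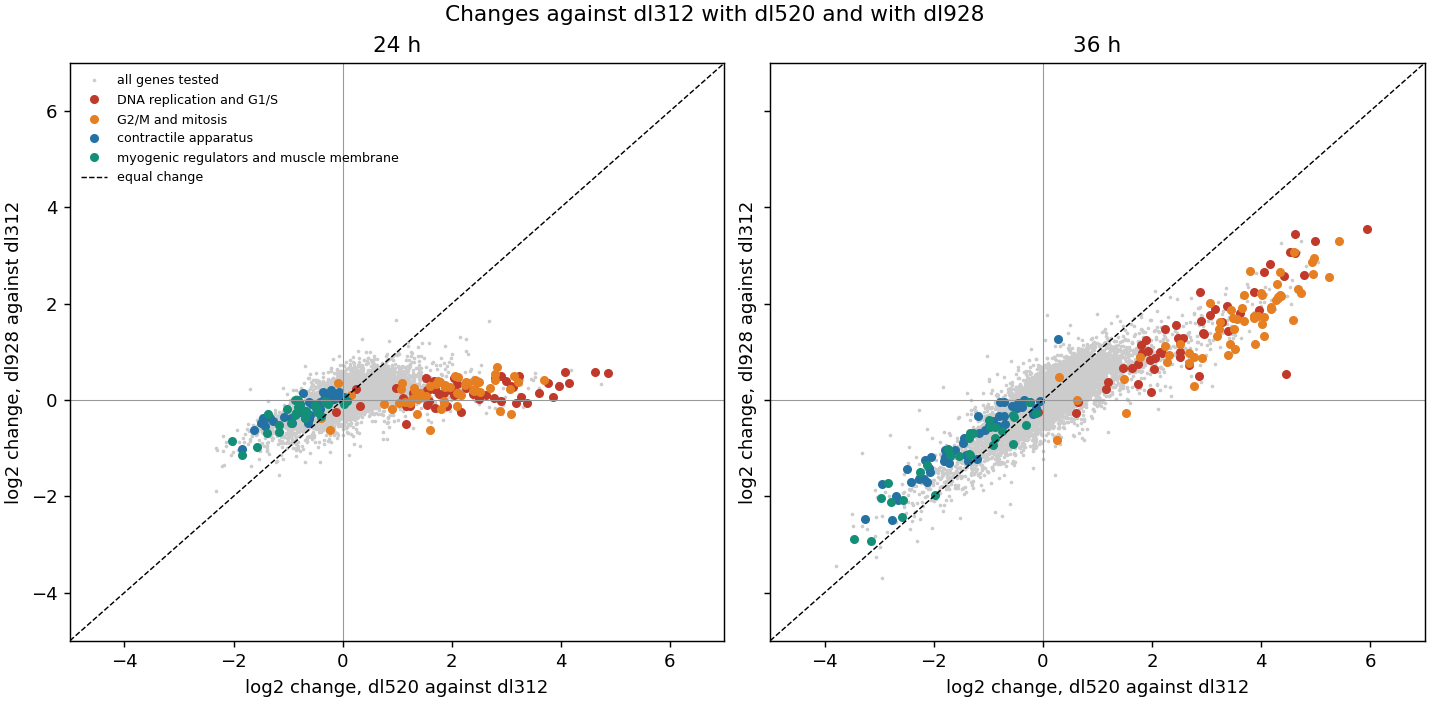
Log2 change with dl928 against dl312 (vertical axis) over that with dl520 against dl312 (horizontal axis) for each gene tested (grey), at 24 h and at 36 h, with 4 gene lists in colour and the line of equal change.

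The comparisons of 36 h with 24 h within a virus ask what changed over the last 12 h. With dl520 the mitotic genes Cenpa (6.02-fold, log2 2.59 ± 0.27), Ccnb2 (5.67-fold, log2 2.5 ± 0.32), Cdca3 (5.35-fold, log2 2.42 ± 0.34) and Hmmr (5.09-fold, log2 2.35 ± 0.52) rose the most. The calcium-dependent kinase Camk2a (4.16-fold, log2 -2.06 ± 0.27), Chrne (4.12-fold, log2 -2.04 ± 0.46), Tceal7 (4.05-fold, log2 -2.02 ± 0.34) and Itgb1bp2 (3.92-fold, log2 -1.97 ± 0.18), an integrin partner, fell the most, with adjusted p = 4.56e-04 to 0.0391. At 36 h Chrne lay below the filter threshold. In G2/M and mitosis 29 of 57 rose and 28 did not pass (54 rose adjusted over the list alone), at a median of 1.48. On the mitosis list camera gave adjusted p = 4.03e-41 and adjusted p = 0.20 with an estimated correlation. Of the DNA replication and G1/S genes 2 of 50 rose and 48 did not pass (5 rose adjusted over the list alone). On the replication list camera gave adjusted p = 1.62e-09 and adjusted p = 0.361 with an estimated correlation. The contractile list gave 17 falls among 49 (35 adjusted over the list alone). On the contractile list camera gave adjusted p = 1.16e-30 and adjusted p = 0.125 with an estimated correlation. The myogenic list gave 13 falls among 30 (20 adjusted over the list alone), Myod1 (log2 -1.41 ± 0.29) and Myog (log2 -1.38 ± 0.17) among them. On the myogenic list camera gave adjusted p = 1.62e-23 and adjusted p = 0.119 with an estimated correlation. In all, limma called 308 genes, 120 up and 188 down. The count was 17 without the 24 h replicate 1, 15 without the 36 h replicate 1 and 84 without the 36 h replicate 2. Without dl520 24 h replicate 1, calls were lost for Cdca3, Hmmr, Camk2a, Chrne and Tceal7. The call of Chrne was lost without dl520 24 h replicate 2. Omitting dl520 36 h replicate 1 ended those of Ccnb2, Cdca3, Hmmr, Camk2a, Chrne and Tceal7. Hmmr, Chrne and Tceal7 lost their calls without dl520 36 h replicate 2. The calls of Hmmr and Chrne also ended under other settings (adjusted p = 0.0514 to 0.433 in all).

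With dl928 the largest rises between 24 h and 36 h were those of Ercc6l (8.22-fold, log2 3.04 ± 0.38), Ccne2 (7.7-fold, log2 2.94 ± 0.32), Hmgb2 (7.3-fold, log2 2.87 ± 0.37) and Bub1 (6.84-fold, log2 2.77 ± 0.54). The largest falls were those of Egr3 (7.25-fold, log2 -2.86 ± 0.31), Ly6g2 (5.77-fold, log2 -2.53 ± 0.50), Fam167a (5.22-fold, log2 -2.38 ± 0.34) and Myod1 (5.13-fold, log2 -2.36 ± 0.29), with adjusted p = 7.78e-04 to 0.0107. Ercc6l and Bub1 at 24 h and Ly6g2 and Fam167a at 36 h lay below the filter threshold. Of the DNA replication and G1/S genes, 34 of 50 rose and 16 did not pass (43 rose adjusted over the list alone), at a median of 1.2. Camera for the replication genes gave adjusted p = 1.49e-30 and adjusted p = 0.156 with an estimated correlation. In G2/M and mitosis 31 rose, 1 fell and 25 of 57 did not pass (50 and 1 adjusted over the list alone). Camera for the mitosis genes gave adjusted p = 3.05e-24 and adjusted p = 0.193 with an estimated correlation. The myogenic list gave 19 falls among 30 (24 adjusted over the list alone), with Tead4 (log2 -1.99 ± 0.24) and Myog (log2 -1.97 ± 0.17). Camera for the myogenic genes gave adjusted p = 1.43e-23 and adjusted p = 0.059 with an estimated correlation. The contractile list gave 22 falls among 49 (30 adjusted over the list alone). Camera for the contractile genes gave adjusted p = 2.06e-22 and adjusted p = 0.156 with an estimated correlation. In all, limma called 789 genes, 322 up and 467 down. The count was 97 without the 24 h replicate 1, 466 without the 36 h replicate 1 and 470 without the 36 h replicate 2. Leaving out dl928 24 h replicate 1 ended the calls of Bub1 and Ly6g2. Without dl928 36 h replicate 1, the call of Bub1 was lost. The call of Ly6g2 was lost without dl928 36 h replicate 2. At least 1 other setting ended the calls of Bub1 and Ly6g2 (adjusted p = 0.0515 to 0.162 in all).

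With dl312 no gene passed between 24 h and 36 h in limma, with 582 genes at an unadjusted p under 0.05 (368 without the 36 h replicate 1 and 1904 without replicate 2, when 1 passed). Among all list members the largest values were those of Cxcl5 (log2 2.92 ± 1.43) and Saa3 (log2 2.80 ± 1.44) in the NF-kappaB, cytokine and chemokine list, where replicate 1 at 36 h was high. The list mean of replicate 1 stood 1.39 (log2) above that of replicate 2, with 1.37 in dl928 and 0.198 in dl520 at 36 h. With dl928, Ccl5 (log2 2.48 ± 0.47) and Vcam1 (log2 1.32 ± 0.34) of that list rose from 24 h to 36 h. Camera for the NF-kappaB genes gave adjusted p = 0.18 and adjusted p = 0.742 with an estimated correlation, and adjusted p = 3.37e-05 by camera without the 36 h replicate 2 and 0.0301 with technical arrays B. Ifit1 (log2 2.70 ± 0.51) and Ifit3 (log2 2.37 ± 0.62) of the interferon-stimulated genes also rose. Camera for the interferon genes gave adjusted p = 4.68e-05 and adjusted p = 0.256 with an estimated correlation. The dl928 count between times was 604 without both high samples. Omitting dl928 24 h replicate 1 ended the calls of Vcam1, Ifit1, Ifit3 and Ccl5. Vcam1 and Ifit3 lost their calls without dl928 24 h replicate 2. Leaving out dl928 36 h replicate 1 ended the calls of Vcam1, Ifit3 and Ccl5. Other settings ended the calls of Ccl5, Vcam1, Ifit1 and Ifit3 (adjusted p = 0.0522 to 0.295 in all).

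**Figure D4:**
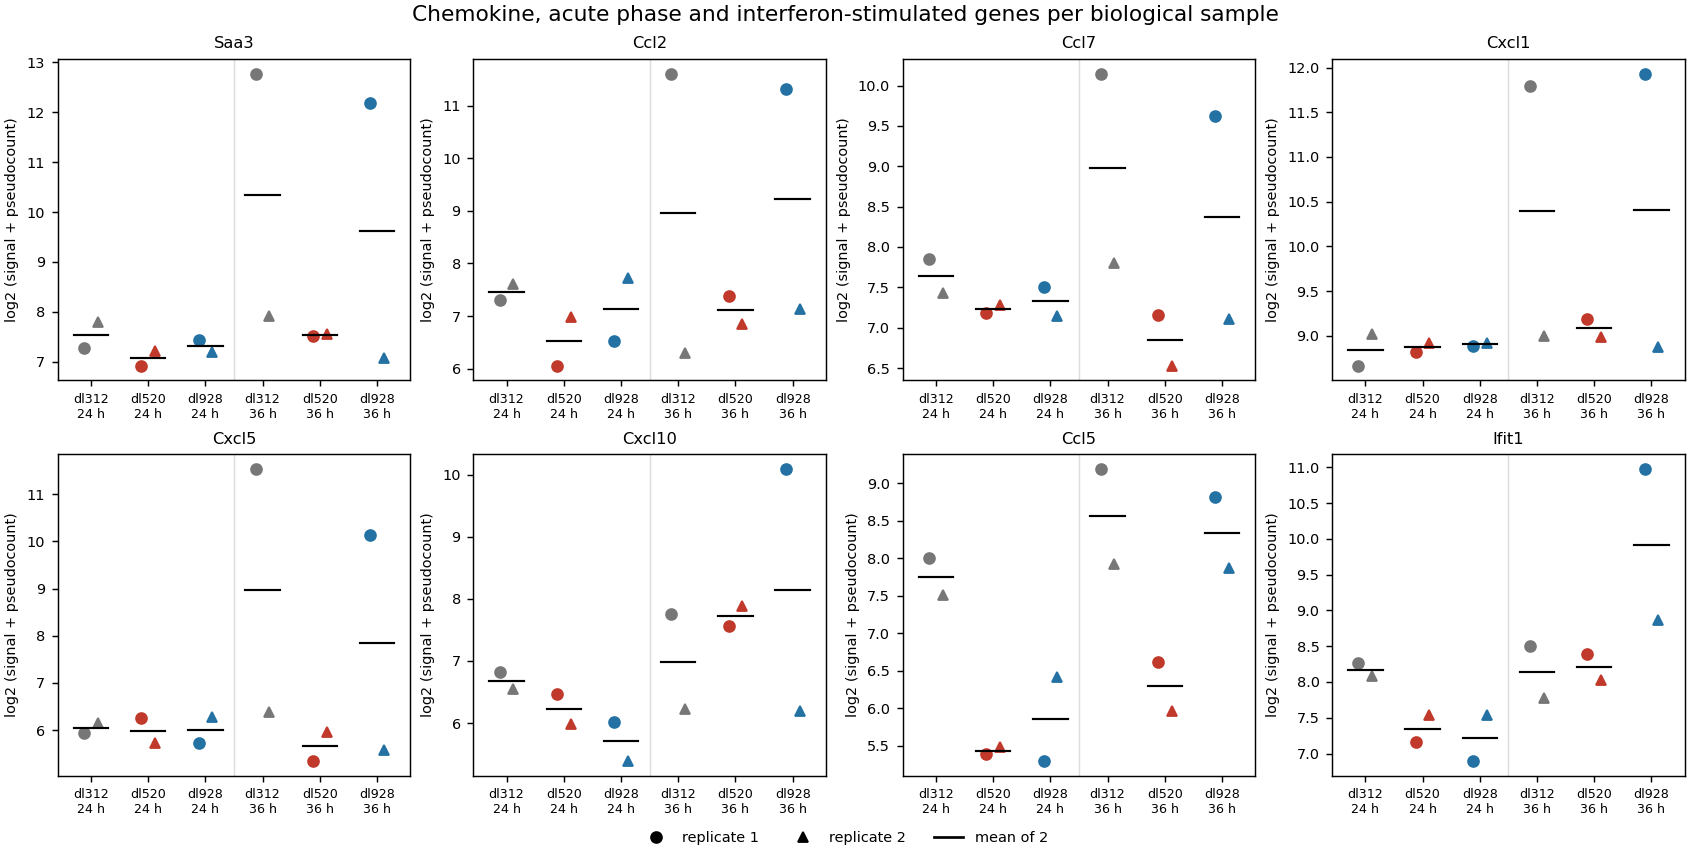
Log2 signal of Saa3, Ccl2, Ccl7, Cxcl1, Cxcl5, Cxcl10, Ccl5 and Ifit1 in each of the 12 samples (points), by virus and time, with group means as bars.

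Whether the effect of a virus differed between 36 h and 24 h was tested as a difference of differences. For dl520 against dl312, limma called 6 genes, with rises larger at 36 h for Cenpa (log2 2.73 ± 0.37) and Wnt7a (log2 2.06 ± 0.30) and falls larger at 36 h for the muscle genes Itgb1bp2 (log2 -2.15 ± 0.25), Cacng1 (log2 -1.53 ± 0.23), Synpo2l (log2 -1.51 ± 0.20) and Chrng (log2 -1.47 ± 0.22), at adjusted p = 0.0221 to 0.0497. For dl928 against dl312 it called 44, 18 up and 26 down, with Gins2 (log2 3.14 ± 0.45), Ercc6l (log2 3.04 ± 0.54), Cenpi (log2 2.96 ± 0.52) and Ccne2 (log2 2.90 ± 0.45) as the largest rises and Ank1 (log2 -2.16 ± 0.29), Bex1 (log2 -2.06 ± 0.37), Nmrk2 (log2 -2.04 ± 0.36) and Tead4 (log2 -1.92 ± 0.34) as the largest falls, at adjusted p = 0.026 to 0.0409. For dl520 against dl928 no gene passed in limma, with 861 at an unadjusted p under 0.05, and 1 passed without dl928 24 h replicate 2. The count of 6 became 0 to 22 and the count of 44 became 0 to 84 with 1 sample left out, and each of these named calls was lost without at least 1 sample (adjusted p up to 0.306 for Cacng1 without dl520 24 h replicate 1, and up to 0.245 for Ercc6l and Tead4 without dl928 24 h replicate 1). Without the 2 samples with high chemokine genes the counts were 0 (limma) and 1.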

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

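The test of the spread of the dl928 samples was chosen after the result was seen. The effect of a virus differed between 36 h and 24 h by a direct test for 6 genes with dl520 against dl312, Cenpa (2.73), Wnt7a (2.06), Itgb1bp2 (-2.15), Cacng1 (-1.53), Synpo2l (-1.51) and Chrng (-1.47, log2). For dl928 against dl312 it differed for 44 genes, with Gins2 (3.14), Ercc6l (3.04), Cenpi (2.96), Ccne2 (2.90), Ank1 (-2.16), Bex1 (-2.06), Nmrk2 (-2.04) and Tead4 (-1.92) as the largest. Each of these 14 calls was lost without at least 1 sample and under another setting, and both counts were 0 in limma without a trend (1103 and 1305 genes at an unadjusted p under 0.05). Probe sets without a single gene symbol, which the comparisons did not use, were called in numbers of 92 and 396 with dl520 against dl312 at 24 h and 36 h, 145 with dl928 against dl312 at 36 h, and 17 and 30 with dl520 against dl928 at 24 h and 36 h, of 3350.

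No gene passed in limma with dl928 against dl312 at 24 h (905 at an unadjusted p under 0.05), while 2578 passed at 36 h. A gene's standard error was the same at both times, so a larger spread as the cause is argued against. Replicate differences had an SD of 0.327 in dl928 at 24 h (others 0.291 and 0.312) and 0.327 to 0.405 at 36 h. A mislabelled dl312 sample is argued against by the share of the 36 h genes that moved the same way at 24 h, 80.9% in the lower dl928 sample against 53.2% for the difference of the dl312 replicates. The same change with a later start may explain the pattern, since the 24 h changes of those genes correlated with the 36 h changes at r = 0.81, with a slope of 0.28. The median change towards the 36 h direction was 0.162 in replicate 1 and 0.364 in replicate 2 of dl928 at 24 h. The 24 h and 36 h changes use different samples, controls included. A smaller effect of the mutant at 24 h for another reason than a later start was not tested and stays open.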

How the results depend on the processing

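The tests without the 2 samples with high chemokine genes and with a crossed pairing were chosen after the data were seen. Of 238 counts of called genes under the alternatives, 173 stayed at 0 or lay within 1.5 times the value reported. Of 2940 list medians, 2804 kept their side of the threshold, 70 lost and 60 gained a call and 6 called ones reversed. Of 16651 named and listed gene values, 15084 did, 1420 lost and 147 gained a call and 0 called ones reversed in limma. With 1 sample left out, the lone sample being assumed to vary like the other groups, the counts were 509 to 1376 (dl520 against dl312 at 24 h), 2738 to 3722 (36 h), 1340 to 2449 (dl928 against dl312 at 36 h), 123 to 542 (dl520 against dl928 at 24 h) and 171 to 591 (36 h). Between times they were 0 to 1 (dl312), 15 to 364 (dl520) and 97 to 744 (dl928), and for the difference between times 0 to 22 (dl520 against dl312), 0 to 84 (dl928 against dl312) and 0 to 1 (dl520 against dl928). The counts depended on which sample was left out, and the cause was not tested. The other counts concern the times within a virus and the difference between times (below, the difference) unless a comparison is named. Without a pseudocount the difference for dl520 against dl312 was 2, and with 4 times the pseudocount that for dl928 against dl312 was 17. With no filter dl520 between times gave 197 and the differences 1 (dl520) and 4 (dl928), and at the 75th percentile the dl520 difference was 10. It was 10 with median centring, and 1 with the mean of probe sets. Technical arrays A alone gave 196 for dl520 between times and 12 for the dl928 difference, which was 21 with arrays B. In limma without a trend dl520 between times gave 165 and the differences 0 and 0 (1103 and 1305 genes at an unadjusted p under 0.05). The 24 arrays with duplicateCorrelation gave 16 genes for dl928 against dl312 at 24 h, 1021 and 1304 for dl520 against dl928 at 24 h and 36 h, 4, 879 and 1522 between times for dl312, dl520 and dl928, and 226, 461 and 41 for the 3 differences. The replicate numbers were not taken to pair samples, as only 6 of 15 correlations of replicate differences between groups exceeded 0.1 (-0.107 to 0.397). At 24 h 3 of 3 did (0.185 to 0.268) and at 36 h 1 of 3, so a pairing at 24 h stays open. The replicate block gave 37 and 164 for the differences of dl520 and dl928 against dl312, and kept the other counts within 1.5 times. Fits of only the groups compared gave 1198 for dl928 against dl312 at 36 h, 237 for dl928 between times and 11 for the dl928 difference. Without both samples with high chemokine genes the count of dl928 against dl312 at 36 h was 1606, and the differences were 0 in limma (1171 genes at an unadjusted p under 0.05) and 1. In the fit of the 4 samples of dl520 and dl928 at 36 h, the crossed pairing gave 597 genes and the pairing by replicate number 444. The median of mitochondrial respiration reversed under quantile normalization to 0.0351 (dl520 against dl312 at 24 h), 0.00593 (dl928 against dl312 at 36 h) and 0.0289 (dl520 against dl928 at 24 h), and that of heat shock genes to 0.00157 (dl520 against dl312 at 36 h). For dl928 against dl312 at 24 h, leaving out 1 sample gave a contractile median of -0.162 to 0.049 and a p53 target median of -0.123 to 0.00551, above 0 without dl928 24 h replicate 2. The cause of these changes was not tested. Signals below the threshold of 125.2 limit the folds of dim genes.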

Other observations

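The tests of a shared day, of a lowering by 12S E1A and of a delayed response were chosen after the results were seen. In replicate 1 at 36 h of dl312 and of dl928, but not of dl520, genes such as Saa3, Ccl2, Ccl7, Cxcl1 and Cxcl5 were high, and the 20 measured NF-kappaB, cytokine and chemokine genes exceeded replicate 2 by a mean of 1.39 and 1.37 (log2). Single arrays are argued against, as the 4 arrays of these samples lay at least 0.956 above the other 20. Immune cells stay open, as the median of 17 macrophage markers differed by 0.0186 and -0.06 from the other samples, but only 6 of them reached the signal threshold and these went both ways (log2 -0.22 to 0.67 in dl312 and -0.68 to 0.24 in dl928). The bound set beforehand, a median under 0.3, was met but decides nothing on markers near the floor, and other immune cells were not tested. A shared day as the whole cause and a lowering of these genes by 12S E1A could not be told apart. Their mean in dl520 replicate 1, 1 sample, lay 0.198 above replicate 2 and at -1.53 from the mean of the other viruses. Over all genes replicate differences at 36 h correlated at 0.397 (dl520, dl312), -0.107 (dl520, dl928) and -0.028 (dl312, dl928).

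Set against dl520 at 24 h, dl928 at 36 h had a lower median of replication genes (-0.86) and of myogenic genes (-0.27). Array scaling is argued against, as the smallest ratio of these differences under other scalings to those as deposited was 1.01. By limma 0 of 113 muscle genes fell further and no gene passed (748 at an unadjusted p under 0.05, smallest adjusted p = 0.261), while by camera the lists had adjusted p = 1.11e-30 and adjusted p = 2.08e-05, and adjusted p = 0.259 and adjusted p = 0.337 with an estimated correlation. The response to dl520 with a delay in dl928 and a different balance of replication and muscle genes could not be told apart with 2 samples per group, since a p that misses the threshold does not show equality.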
